A study of Mus musculus with 4 samples.

How the data were processed

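Colonic epithelium scraped from adult mice of 2 to 4 months was profiled by ChIP-seq, which sequences the DNA bound by an antibody's target. The 4 groups had 1 library each, per the labels: H3K27ac and HNF4A, each from mice given water only and from mice given 3% dextran sulfate sodium (DSS) for 6 days. The submitters' processing notes name CASAVA 1.8.2, MACS2 and the mouse build mm9. The names of the deposited HNF4A peak lists tie MACS2 to those lists and carry short codes that read like cut-offs, whose meaning they do not explain. The role of CASAVA and any pooling of animals are not given in the sources used here.

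For H3K27ac the authors deposited 2 lists of 1000 regions, and the list names describe them as the regions most enriched in water or in DSS and lying at least 2 kb away from an unnamed feature. Both lists carry raw tag counts in both libraries, per the file headers, which mark the reads as MAPQ20, read here as a mapping quality of at least 20. The count columns are headed "nuc" and "lin", read here as tags on the nucleosomes of a region and on the linker between them. Columns headed WT were read as the water library and those headed DSS as the DSS library. The header of the DSS column also carries "r2", which the sources used here do not explain. The deposited score of a region, headed NSD, was rebuilt exactly from the counts: the square root of the nucleosome count minus that of the linker count, divided by the square root of a library total, in DSS minus water. That relation gave the library totals, 10329416 tags for DSS and 10143920 for water, and the same totals came from both lists. A further column, which the header calls "id", moved by the distance between region centres in 159 of 159 neighbouring pairs of the water-enriched list and in 109 of 112 of the DSS-enriched list (tolerance 2 bp, pairs within 3 kb). It was therefore read as the distance in bp to the nearest reference point, which the header does not name. For HNF4A the authors deposited 1 peak list per library, with peaks of 600 bp sorted by a score whose kind the files do not state. These peak scores were used only to rank peaks within a list, except in the alternative with a common score threshold. The depth of the HNF4A libraries is unknown from these files.

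Tag counts were scaled by the library totals. The ratio of the libraries in a region was given with its exact conditional (Clopper-Pearson) 95% interval, and log2 ratios used a pseudocount of 0.5. Peaks and regions were called overlapping when they shared at least 1 bp. Shares were given with Wilson 95% intervals, and differences of shares with Newcombe intervals. All these intervals cover counting error only. Differences beyond them are not shown to hold between animals, since each group had 1 library and no p-value can be given. The overlaps were set beside 1000 random placements of the same intervals on the same chromosomes, within the span of the water peaks for DSS peaks and within the span of the 4 lists for H3K27ac regions. The difference in occupancy was set beside 10000 relabellings of the 2 lists' regions. The placements were spread evenly over these spans and take no account of mappable or open chromatin. These placements and relabellings describe the lists and are not replicate tests. Bootstrap intervals came from 1000 draws for medians, turnover and score-matched peaks, 300 for rank correlations, and 2000 for differences matched in 5 bins and for linker ratios. Score-matched peaks were compared in 20 bins of score. The distance interval in the turnover comparison was 10 kb.

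The functions were tested on simulated data built on these lists. All 9921 peaks planted as shared were recovered among 16443 merged water peaks. They were shifted by less than a peak width, so this checks the code only. Counts were simulated for 1000 regions from the water nucleosome counts of the water-enriched list. There 95.4% of the ratio intervals held the true ratio and all 200 regions changed 2-fold were recovered. Of the 800 unchanged regions, 4.63% had an interval that left out 1. The lower counts of linker tags and of DSS-enriched regions were not simulated.

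The regions and peaks named were chosen by a rule fixed before the data were examined: the 15 regions with the highest absolute score per H3K27ac list, of which the first 5 are described, and the 5 strongest peaks per class, of which the first 3 are described. The same holds for the comparisons and most alternatives. Alternatives covered the overlap rule, the score threshold, equal list lengths, the top 500 regions, a fixed width of 1 kb and the spacing limits; merged intervals and removal of dense windows were added after the data were seen. Dense windows were 100 kb bins with 10 or more water HNF4A peaks. The only gene table at hand is of another build: the largest HNF4A peak end on chromosome 1 (197068113) lies past its last gene there (195291439). Regions were therefore not assigned to genes, and the planned gene lists and sequence motifs were not analysed here. HNF4A peak coordinates are printed 1-based in mm9, and H3K27ac coordinates as deposited, since their header does not say how positions are counted. No list of regions prone to artefact signal was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.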

Results

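To compare chromatin between healthy and inflamed colon, H3K27ac and HNF4A were mapped by ChIP-seq in colonic epithelium of mice given water or DSS, a chemical that injures the colonic lining and causes colitis. H3K27ac is an acetylation of histone H3 found on active enhancers and promoters, and HNF4A is a nuclear receptor that binds DNA and drives genes of differentiated intestinal epithelium. The design held 4 groups of 1 library each. The H3K27ac libraries held 10329416 tags in DSS and 10143920 in water, so their depths were nearly equal. The HNF4A lists held 17886 peaks in water and 10688 in DSS. No comparison has a replicate check, and all intervals given are 95% intervals that cover counting error only.

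The first question was where H3K27ac differed between water and DSS epithelium away from the 2 kb around the authors' reference points. In the 1000 water-enriched regions, nucleosome tags were 1.88-fold higher in water at the median, with a median log2 ratio of DSS to water of -0.91 (quartiles -1.20 and -0.70). In the 1000 DSS-enriched regions they were 2.66-fold higher in DSS, with a median log2 ratio of 1.41 (quartiles 0.95 and 2.03). The water-enriched regions were strongly acetylated in both libraries, with median counts of 265.5 nucleosome tags in water and 137.5 in DSS. The DSS-enriched regions held fewer tags in both, with medians of 38 tags in water and 106 in DSS. More than 2-fold differences in nucleosome tags were found in 401 water-enriched and 715 DSS-enriched regions. The interval of the ratio left out 1 in the listed direction in 993 water-enriched and 958 DSS-enriched regions. Both lists were chosen by the authors on these same counts, so these numbers describe the lists and are not independent evidence of change.

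Linker tags went the other way from nucleosome tags at the median of both lists. Water-enriched regions had a median log2 linker ratio of DSS to water of 0.46 (quartiles -0.04 and 1.33), and DSS-enriched regions had -0.66 (quartiles -1.61 and -0.03). The linker counts behind these ratios were low, with medians between 4 and 10 tags per region and library, and the interval of the linker ratio held 1 in 817 water-enriched and 791 DSS-enriched regions. The deposited score subtracts linker from nucleosome signal and therefore favours regions in which the linker moves oppositely. Counting all tags of a region instead, the interval lay on the water side in 969 water-enriched regions and on the DSS side in 864 DSS-enriched regions. Among the other DSS-enriched regions, 110 had intervals that held 1 and 26 held more tags in water.

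**Figure D1:**
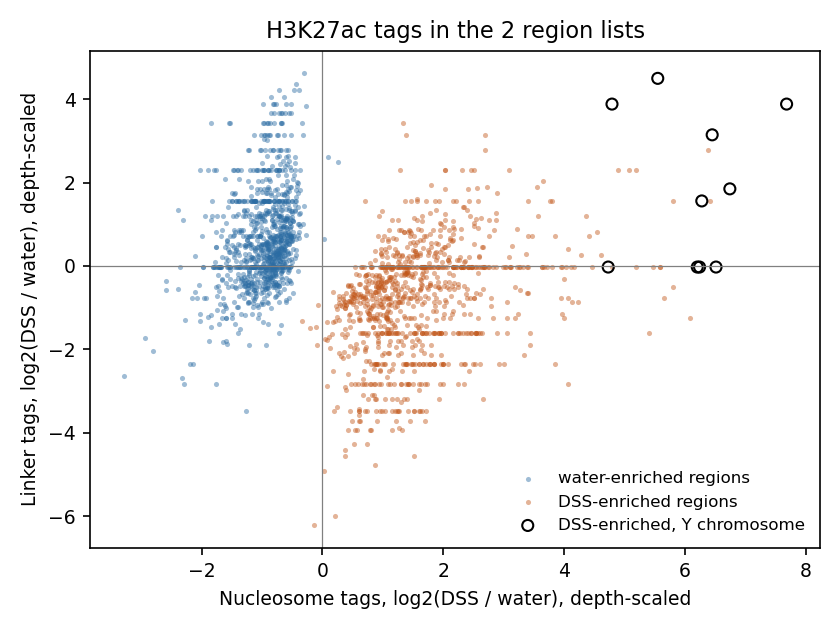
Each point is one H3K27ac region, with the log2 ratio of DSS to water of its nucleosome tags on the x axis and of its linker tags on the y axis, both scaled by library total with a pseudocount of 0.5. Water-enriched regions (blue) centre on -0.91 and 0.46, DSS-enriched regions (orange) on 1.41 and -0.66, and the 10 Y chromosome regions are circled.

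The water-enriched region of highest score lay on chromosome 16 (92148171 to 92148716) and held 506 nucleosome tags in water against 67 in DSS, a 7.69-fold difference (interval 5.95 to 10.1). It overlapped an HNF4A peak in water, ranked 13168 of 17886, and none in DSS. A region on chromosome 3 (122591086 to 122591676) held 1186 tags in water and 554 in DSS, which is 2.18-fold higher in water (1.97 to 2.42). It overlapped an HNF4A peak in the DSS list alone, ranked 9824 of 10688. A water-enriched region that overlaps it (122590761 to 122591286), also among the 15 of highest score, held a DSS peak of the same rank and a water peak ranked 11928. The region on chromosome 3 at 96379106 to 96379671 held 1341 and 692 tags, 1.97-fold higher in water (1.8 to 2.17), with an HNF4A peak in both lists. A region on chromosome 1 (152589441 to 152590001), 250844 bp from its reference point, was 5.26-fold higher in water (3.91 to 7.21) and held no HNF4A peak. The region on chromosome 11 at 109049016 to 109049641 was 5.18-fold higher in water (3.98 to 6.84) and overlapped an HNF4A peak in water alone, ranked 6206. Of the 15 water-enriched regions of highest score, 9 overlapped a water HNF4A peak and 6 overlapped a peak in both lists. Some of these 15 regions overlap each other and share peaks, so they are not all separate sites.

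The DSS-enriched region of highest score lay near the start of chromosome 18 (3005331 to 3005961), with 2955 nucleosome tags in DSS and 1355 in water, a ratio of 2.14 (2.01 to 2.29). It and the next region, on chromosome 15 (74916726 to 74917261, ratio 2.94, interval 2.62 to 3.31), overlapped some of the strongest HNF4A peaks. These ranked 36 and 7 in the water list and 31 and 7 in the DSS list. Neither site was checked against known regions of artefact signal. A region on chromosome 9 (35228761 to 35229401) held 228 tags in DSS and 21 in water, a ratio of 10.7 (6.81 to 17.6), with no HNF4A peak. Regions on chromosome 10 (129979076 to 129979606, ratio 2.32, interval 2.02 to 2.67) and on the X chromosome (166435326 to 166435866, ratio 5.91, interval 4.51 to 7.86) also held no HNF4A peak; the X region lies in a 100 kb window crowded with 10 or more water HNF4A peaks. Of the 15 DSS-enriched regions of highest score, 5 overlapped a water HNF4A peak and 3 overlapped a peak in both lists. Here too some of the 15 regions overlap each other.

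The lists lay at similar distances from their reference points, with medians of 23.2 kb for water-enriched regions (quartiles 9.34 and 52.4) and 21.7 kb for DSS-enriched regions (quartiles 8.89 and 45.3). Regions of one list were clustered. Within 10 kb of another region of the same list lay 367 of the water-enriched regions, against a mean of 8.62 in random placements, and 245 of the DSS-enriched regions, against 9.24. Part of this count came from regions that overlap each other: after merging them the shares dropped from 36.7% to 16.9% of 876 regions and from 24.5% to 13.3% of 930. The largest groups of merged water-enriched regions, linked at gaps of up to 50 kb, held 6 regions over 115 kb of chromosome 4 (55616481 to 55731861) and 6 over 50.3 kb of chromosome 6 (52198701 to 52248971). The largest group of DSS-enriched regions held 7 regions over 29.7 kb of chromosome 6 (82697666 to 82727341). The group on chromosome 4 contained 10 water and 6 DSS HNF4A peaks, and the water-enriched group on chromosome 6 contained 4 and 3. The DSS-enriched group on chromosome 6 contained 2 water and 0 DSS peaks, and the next DSS-enriched group, 5 regions on chromosome 12 (112666501 to 112676816), contained 1 and 2. Regions of opposite direction also lay near each other more often than random placements: 47 water-enriched regions were within 10 kb of a DSS-enriched one, against a mean of 7.61. This count was not reduced for overlaps between the lists. Directly overlapping a DSS-enriched region were 11 water-enriched ones, in which total tags differed little between libraries (median log2 ratio -0.31). On the Y chromosome lay 10 DSS-enriched regions and 0 water-enriched ones, and on the X chromosome 11 and 13. A possible difference in sex between the mice of the H3K27ac libraries, taken up below, could also affect other regions of both lists.

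The next question was how HNF4A binding differed between water and DSS epithelium. The water list was 1.67 times as long as the DSS list. Most DSS peaks lay on water peaks: 8795 of 10688 (82.3%, interval 81.6 to 83.0) overlapped one, against a mean of 92.3 in random placements. Of the 17886 water peaks, 9468 (52.9%, interval 52.2 to 53.7) overlapped a DSS peak, which left 8418 water-only and 1893 DSS-only peaks. With the water list held to its 10688 highest peaks, 69.9% of water peaks and 69.4% of DSS peaks were shared.

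The strongest peaks were shared almost completely. In the highest decile of water scores, 97.9% of peaks (97.1 to 98.4) overlapped a DSS peak, against 21.4% (19.6 to 23.4) in the lowest decile. In the DSS list the shares were 97.0% (95.8 to 97.9) and 60.5% (57.6 to 63.4). Water-only peaks sat at a median rank percentile of 32.0 in the water list (interval 31.2 to 32.6), and DSS-only peaks at 26.0 in the DSS list (24.3 to 27.4), where 100 is the strongest. None of 10000 random sets of the same size had a median score as low in either list. Across 8627 pairs of shared peaks, the scores of the libraries correlated with Spearman's rho of 0.62 (0.60 to 0.63). This correlation is across peaks, which are not independent replicates.

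**Figure D2:**
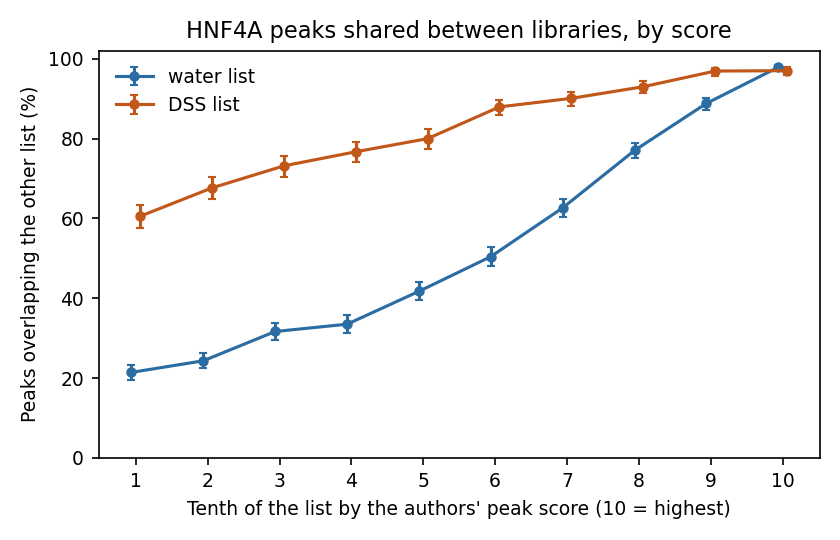
Share of HNF4A peaks that overlap a peak of the other library (y axis, percent) for each decile of the authors' peak score within a list (x axis, 10 is the highest), with Wilson 95% intervals. Sharing of water peaks goes from 21.4% in the lowest to 97.9% in the highest decile, and that of DSS peaks from 60.5% to 97.0%.

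The 5 strongest peaks of the water list were also the 5 strongest of the DSS list. The first 3 in water lay on the X chromosome (139917300 to 139917899, score 172), on chromosome 12 (3109745 to 3110344, score 150.5) and on chromosome 4 (70038934 to 70039533, score 148). The strongest in DSS lay on chromosome 9 (35112695 to 35113294, score 207). Strong peaks of 1 list alone were few: the highest water-only peaks ranked 42 (chromosome 2, 98506150 to 98506749), 118 (chromosome 10, 21861847 to 21862446) and 216 (chromosome 2, 98506325 to 98506924) in the water list, and the peaks on chromosome 2 overlap each other. The highest DSS-only peaks ranked 104 (chromosome 9, 120868948 to 120869547), 111 (chromosome 11, 75565179 to 75565778) and 117 (chromosome 14, 21523219 to 21523818) in the DSS list. None of the peaks named here lay in a dense window. They were not checked against known regions of artefact signal, so they may not all be HNF4A binding.

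HNF4A binding and H3K27ac were then joined, to ask whether regions that differed in acetylation held HNF4A. Water-enriched regions were occupied by HNF4A more often than DSS-enriched regions in both libraries. In water, 45.9% of water-enriched regions (42.8 to 49.0) and 20.8% of DSS-enriched regions (18.4 to 23.4) overlapped a peak, a difference of 25.1 points (21.1 to 29.0). In the DSS library the shares were 32.9% (30.1 to 35.9) and 13.9% (11.9 to 16.2), a difference of 19.0 points (15.4 to 22.6). The shares themselves depended on the peaks counted. With peaks within 2 kb, 60.9% of water-enriched and 38.2% of DSS-enriched regions had a water peak, and 44.9% and 27.8% a DSS peak. With peaks above the pooled median score alone, the shares were 28.3% and 10.5% in water and 22.1% and 8.4% in DSS. None of 10000 relabellings of the regions gave a difference as large, and the largest were 8.3 and 7.2 points. Random placements reached mean shares between 0.50% and 0.80%, so both kinds of region lay on HNF4A peaks far more often than evenly spread positions. Shared mappable or open chromatin could raise any such overlap, and regions of unchanged H3K27ac were not available for comparison.

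The lists also differed in tag level, which moved with occupancy: water-enriched regions held a median of 432 H3K27ac tags over both libraries and DSS-enriched regions 164. In the highest quintile of tags, 61.4% of 334 water-enriched regions (56.1 to 66.4) and 39.4% of 66 DSS-enriched regions (28.5 to 51.5) overlapped a water HNF4A peak. In the lowest quintile the shares were 19.0% of 21 regions (7.67 to 40) and 7.69% of 377 (5.41 to 10.8). For DSS peaks the shares were 48.8% (43.5 to 54.1) and 24.2% (15.5 to 35.8) in the highest quintile, 33.2% (27.96 to 38.9) and 21.5% (15.1 to 29.6) in the next. In the lower quintiles they did not differ beyond their intervals: 23.2% (18.2 to 29.2) and 22.3% (16.8 to 29.0), 14.9% (9.95 to 21.7) and 16.5% (12.5 to 21.4), and 0% (0 to 15.5) and 3.98% (2.43 to 6.46) in the lowest. With the regions matched on tags in 5 bins and the bins weighted by their DSS-enriched regions, the difference was 10.5 points for water peaks (3.96 to 18.8) and 1.29 points for DSS peaks (-1.52 to 4.32). For DSS peaks, Mantel-Haenszel weights, which use the regions of both lists, gave 6.33 points (2.17 to 10.5).

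**Figure D3:**
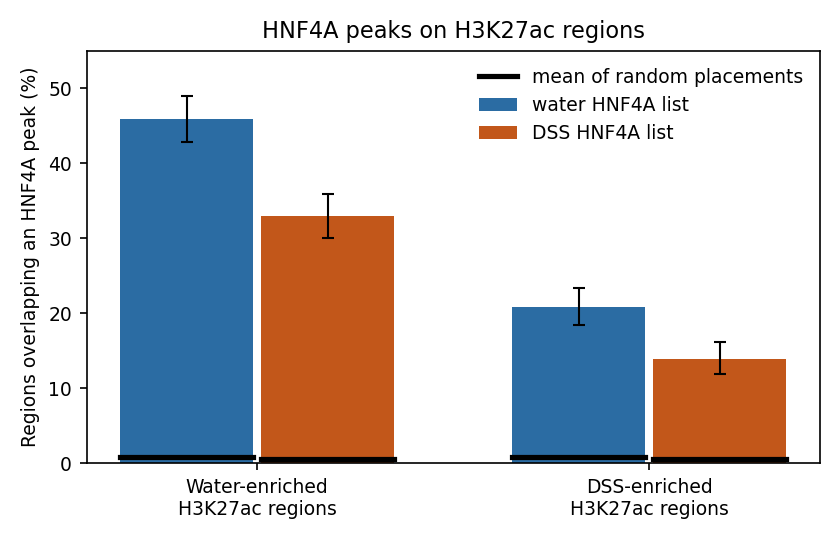
Share of H3K27ac regions that overlap an HNF4A peak (y axis, percent) for water-enriched and DSS-enriched regions (1000 each), by HNF4A library, with Wilson 95% intervals. Black lines mark the mean of 1000 random placements; occupancy is 45.9% and 32.9% in water-enriched and 20.8% and 13.9% in DSS-enriched regions.

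**Figure D4:**
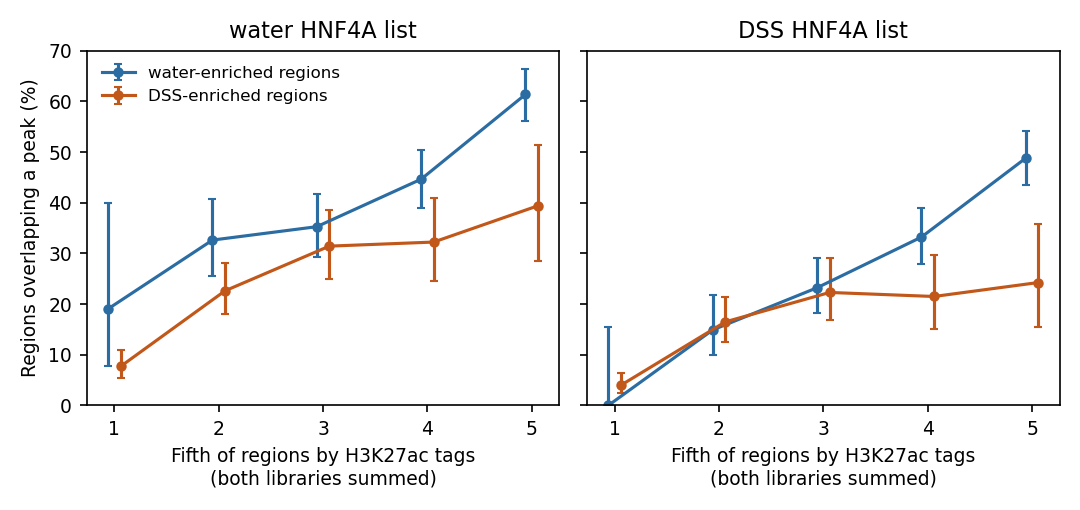
Share of regions that overlap an HNF4A peak of the water list (left) or the DSS list (right) by quintile of H3K27ac tags summed over both libraries, with Wilson 95% intervals. In the highest quintile the water-list shares are 61.4% of water-enriched and 39.4% of DSS-enriched regions.

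Fewer regions of both directions held an HNF4A peak in DSS than in water, where the DSS peak list was the shorter one and the depth behind it is unknown. With the water list held to the length of the DSS list this drop was gone. Then 33.8% of water-enriched regions (30.9 to 36.8) held a water peak against 32.9% with a DSS peak. For DSS-enriched regions the shares were 13.6% (11.6 to 15.9) and 13.9%. Equal lengths would also hide a loss spread over all sites, so these values do not separate list length from lost binding. Of the 459 water-enriched regions with a water peak, 305 (66.4%, interval 62.0 to 70.6) also held a DSS peak, and of the 208 such DSS-enriched regions, 118 (56.7%, 49.9 to 63.3) did. The share still occupied was 9.72 points higher in water-enriched than in DSS-enriched regions (1.8 to 17.7). Water peaks on water-enriched regions were also the stronger ones, with a median rank percentile of 60.8 against 53.1 on DSS-enriched regions. Beside water peaks of the same score elsewhere, the share found again in DSS was 7.28 points higher on water-enriched (3.46 to 11.1) and 3.56 points higher on DSS-enriched regions (-2.55 to 9.31), and the difference between these was not tested. The unmatched difference was not resolved when peaks within 2 kb counted or when only peaks above the pooled median score were used, with values of 5.52 and 7.28 points. With the 500 highest-scoring regions of each list it was 15.5 points (4.53 to 26.4), the largest of the alternatives. A DSS peak without a water peak was held by 24 water-enriched and 21 DSS-enriched regions, against 154 and 90 with a water peak alone. At equal list lengths these counts were 61 and 45 with a DSS peak alone and 70 and 42 with a water peak alone. Within 10 kb of a water-enriched region lay 7.2% of shared peaks (6.70 to 7.74), 5.37% of water-only peaks (4.91 to 5.87) and 3.65% of DSS-only peaks (2.89 to 4.59). Near DSS-enriched regions the shares were 5.57% (5.12 to 6.05), 4.30% (3.89 to 4.75) and 4.17% (3.36 to 5.17). For DSS-only peaks the difference between the region lists was not resolved, at -0.53 points (-1.74 to 0.69).

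The authors' score of a region had little relation to its occupancy. In water-enriched regions the share with a water peak was 40.8% (34.9 to 47.0) in the lowest and 51.6% (45.4 to 57.7) in the highest quartile of absolute score, with a Spearman rho of 0.07 across regions (0.01 to 0.13). In DSS-enriched regions these shares were 22.0% (17.3 to 27.5) and 22.8% (18.0 to 28.4), and rho was 0.02 (-0.04 to 0.07). For DSS peaks rho was 0.05 in water-enriched regions (-0.01 to 0.11) and -0.01 in DSS-enriched regions (-0.07 to 0.05).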

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

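The tests on the Y chromosome, on weak peaks under the threshold, on tag level for DSS peaks, the Mantel-Haenszel weights, matching on DSS tags alone and the merging of regions were chosen only after the results had been seen.

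Y chromosome regions stood out because the DSS library held signal far above the water library: 10 DSS-enriched regions lay there, and 9 that do not overlap each other held 498 tags in DSS against 6 in water. The ratio of water to DSS tags was 0.012 (95% interval 0.0045 to 0.027), while the other 990 DSS-enriched regions had a median ratio of 0.45. Chance dropout at the depth of the water library is argued against, since the upper bound of 0.0269 lies below that median and the library totals were nearly equal. A difference in sex between the mice of the H3K27ac libraries remains a candidate explanation, because water tags were near 0 in each Y region (at most 3); a Y chromosome response to DSS is untested, as each group had 1 library. If sex differed, other regions of both lists and the comparisons between the lists may reflect it too, which was not tested.

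The lower number of HNF4A peaks in DSS was weighed as a second pattern. Peaks of the highest water decile were found again in 97.9% of cases and those of the lowest in 21.4%, which is consistent with weak peaks falling under a threshold in a library of lower yield or enrichment. A moderate weakening of HNF4A binding at all sites predicts the same values, and the depth of these libraries is unknown, so both stay open. Causes other than these and the directed loss below were not weighed. Loss directed at regions that lose H3K27ac predicted fewer water peaks found again there, which was not seen. Of the 448 water peaks on water-enriched regions, 66.5% were found again, against 59.2% of peaks of the same score elsewhere. That is a difference of 7.28 points (3.46 to 11.1) in the opposite direction. On DSS-enriched regions the difference was 3.56 points (-2.55 to 9.31). The peaks elsewhere were matched on score and not on H3K27ac level, so these values cannot exclude directed loss.

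The higher HNF4A occupancy of water-enriched regions was weighed next. Distance to the reference point is argued against, with a matched difference of 25.3 points (21.1 to 29.5), as are overlapping regions counted more than once, with 24.9 points after merging (20.6 to 29.0). Tag level may account for part: matching on tags lowered the difference for water peaks from 25.1 to 10.5 points (3.96 to 18.8), or to 10.8 (5.89 to 15.8) with Mantel-Haenszel weights, while matching on DSS tags alone left 20.6 (16.5 to 24.7). For DSS peaks it left 1.29 points (-1.52 to 4.32) or 6.33 points (2.17 to 10.5), depending on the weights, and 13.8 (10.5 to 17.2) with DSS tags alone, so there tag level cannot be told apart from the direction of the H3K27ac difference. At equal DSS tags, water-enriched regions hold more water tags than DSS-enriched ones, because the lists were chosen on the difference between libraries. Matching on DSS tags alone thus left the water tags unmatched and cannot settle the part of tag level. That HNF4A sites preferentially lose acetylation in colitis remains an untested biological explanation. Other explanations were not weighed.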

How the results depend on the processing

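Some alternatives were chosen only after the data had been seen. These were the merging of overlapping peaks or regions and the removal of the mitochondrial chromosome, the Y chromosome and dense windows. So were the tag matching for DSS peaks, the Mantel-Haenszel weights, matching on DSS tags alone and the extra settings of the linker test. The other alternatives were set before. Of the alternative values of the planned comparisons, 44 stayed within the 95% interval of the reported value and 19 moved outside it. Of those with an interval clear of 0, 0 changed sign, but shares and rank percentiles among them could not. Where the interval held 0, the turnover difference of DSS-only peaks went from -0.53 to 0.21 points with direct overlap. For DSS peaks in DSS-enriched regions, rho went from -0.007 to 0.006 with peaks within 500 bp or with merging. Tag matching is outside these counts. Of the alternative values of the occupancy shares within each list, 28 stayed and 20 moved.

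The shared part of the water and DSS HNF4A lists was 50.9% and 81.2% when 50% of each peak had to be covered, 58.7% and 76.1% above the pooled median score, and 69.9% and 69.4% with the water list held to the length of the DSS list. Merging gave 51.4% for water peaks. At equal lengths the median rank percentiles of water-only and DSS-only peaks were 27.5 and 28.02, so DSS-only peaks no longer had the lower median.

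Water-enriched regions were occupied more often under each alternative for overlap, threshold, list length, region set and width: the difference ranged from 17.8 to 27 points for water peaks and from 13.7 to 21.2 for DSS peaks. The low ends, 17.8 and 13.7, came from peaks above the pooled median score, and equal list lengths gave 20.2 points for water peaks. The shares of occupied regions that still held a peak under DSS were 79.3% and 69.1% at equal lengths, against 66.4% and 56.7%. Matching on tags moved the difference most, to 10.5 points for water peaks and 1.29 (-1.52 to 4.32) for DSS peaks, an interval that holds 0. For DSS peaks this depended on the weights, since Mantel-Haenszel weights gave 6.33 points (2.17 to 10.5). The weak relation of score and water peaks in water-enriched regions (rho 0.07) was 0.04 (-0.02 to 0.10) with peaks within 500 bp, an interval that holds 0.

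Shares of regions near another of the same list followed the limit: 33.2% of water-enriched regions at 5 kb, and 51.1% of water-enriched and 39.0% of DSS-enriched regions at 100 kb. Merging gave 16.9% and 13.3% at 10 kb and 26.0% and 24.3% at 50 kb.

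The cause of the remaining moves was not tested. The planned gene lists and sequence motifs, with all their alternatives, were not run, because the gene table used here is of another build. With 1 library per group no replicate can be left out. No paired analysis was possible because each group had 1 library. The unknown depth of the HNF4A libraries limits statements on absent peaks.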

Other observations

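The minimum of 10 linker tags and a pseudocount of 1 in the linker test were chosen only after the result had been seen, as was the rule that all settings had to pass.

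Some regions of opposite direction overlapped each other: 11 water-enriched regions overlapped 12 DSS-enriched ones. In these the total tags differed little between libraries, with median log2 ratios of DSS to water of -0.31 in the water-enriched (quartiles -0.67 and -0.08) and -0.14 in the DSS-enriched members (quartiles -0.61 and 0.33). The linker tags moved oppositely, with medians of 1.33 and -1.07. The corresponding medians of total tags over the whole lists were -0.82 and 1.16.

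Regions without any HNF4A peak had larger median H3K27ac differences than regions with a peak in both libraries. The 771 DSS-enriched regions without a peak had a median log2 nucleosome ratio of 1.52 (quartiles 1.04 and 2.16), against 0.99 (0.67 and 1.47) in the 118 with a peak in both libraries. In water-enriched regions the medians were -0.99 (-1.29 and -0.76) for 517 regions without a peak and -0.81 (-0.99 and -0.65) for 305 with a peak in both. The regions without a peak also held fewer tags, with medians of 143 against 272.5 and of 372 against 605 over both libraries. Both lists were cut on a score built from differences of square roots of counts. Regions with fewer tags therefore needed larger ratios to be listed. For this reason these medians cannot show whether HNF4A is linked to the size of the H3K27ac difference.

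One hypothesis was set before its result was seen: that linker tags fill in where HNF4A is lost. Water-enriched regions whose peak was absent in DSS had a median log2 linker ratio of 0.63, against 0.34 where it was kept, a difference of 0.30 (95% bootstrap interval 0.0043 to 0.54). Against the hypothesis, the 24 water-enriched regions with a peak in DSS alone had the highest median, 0.72, and in DSS-enriched regions the order was the opposite, with -0.90 where the peak was absent and -0.71 where it was kept. Regions without any peak lay at 0.50, and restricting to regions with at least 10 linker tags gave 0.16 (-0.08 to 0.45), while a pseudocount of 1 gave 0.26 with a lower bound of 0. The test as set beforehand passed by a narrow margin and did not pass under these other settings, so the hypothesis stays open.

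Some HNF4A peaks were crowded: the 100 kb window at the start of chromosome 9 (3000001 to 3100000) held 41 water peaks, the most of any window, and 33 windows with 10 or more peaks held 391 water and 215 DSS peaks. The mitochondrial chromosome held 6 water and 10 DSS peaks.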
